A study of Mus musculus with 6 samples.

How the data were processed

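Labelled cells of the Atoh1 lineage were compared on 6 Affymetrix Mouse Genome 430 2.0 arrays, 3 for cells labelled with tamoxifen at E10.5 (early) and 3 for cells labelled at E13.5 (late), all sorted for EGFP at E14.5. Per the labels' protocols, the r1/isthmus region was dissected from fluorescent embryos, dissociated with papain and DNase, sorted, and total RNA from frozen pellets was biotin-labelled for hybridisation. The deposited values are intensities, 1 MAS5 signal per probe set and array, per the submitters' processing notes, which name MAS5; its version, its detection calls and any pooling are not given in the sources used here. From the values, each array had been scaled so that the mean of its signals without the lowest and highest 2% was 500, on a linear scale with no centring per probe set. Because every array was scaled to the same trimmed mean, a change in the total RNA per cell cannot be read from these signals. MAS5 subtracts mismatch signals, so low values vary strongly on the log scale.

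The table held 45101 probe sets. Gene names came from the platform annotation given with the files: 34958 probe sets named 1 gene symbol, 932 named several and 9211 named none, and no symbol needed an update through the gene number (204 were not found in the gene table). The 64 Affymetrix control probe sets were left out of the tests, and no gene was named from a probe set with several symbols. A gene was represented by its single-gene probe set with the highest mean log2 signal. Of 5026 genes with at least 2 tested probe sets, 42 (0.84%) had probe sets that passed in opposite directions. Of the 102 genes chosen by the rule below, none was among them, but only 40 had another tested probe set. In 32 of these another probe set passed in the same direction. The calls of Rab3c, Slc1a3, Pdgfra, Csf1r, Nos1 and Cdc25c were not shared by any other tested probe set of the gene. Genes of the lists without such a probe set in the table were not analysed here.

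Log2 signals were compared with limma 3.58.1 (lmFit and eBayes, 2.26 prior degrees of freedom) in R 4.3.3, early minus late, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe set was tested if it lay above its array's median (the 50th percentile) in at least 3 of the 6 arrays. Means are given with the SD over 3 arrays, log2 differences with limma's standard error, and folds are 2 to the power of the mean log2 difference. The median log2 difference over tested probe sets was -0.09. The 20 gene lists and 8 lists of markers of other cell types were fixed before the data were examined, as were the test, the rule for naming genes and all alternatives except those listed as added. Each list with at least 3 tested genes was tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 25 lists; camera with an estimated correlation and fry were alternatives. Camera compares a list with the other genes, while fry asks whether its genes move on balance in 1 direction. With an estimated correlation camera also tests on the few residual degrees of freedom of the 6 arrays. Its p-values can therefore rise even where the estimate lies below 0.01, and a lost call is not due to correlation alone. The named genes were the 12 with the largest difference in each direction among genes past the threshold whose 3 arrays of 1 group all lay above those of the other, Atoh1, and up to 4 of the largest differences past the threshold in each list, or up to 2 as values where none passed. Clone and provisional symbols were left out.

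The test was tried on simulated arrays built from the real means and spreads. Noise was drawn independently for each probe set, with 1 spread for both groups. The real early arrays spread more than the late ones (median SD 0.386 against 0.212 on the log2 scale), so the rates may differ for the real data. With 50 probe sets changed at each size among 22597 tested, 0%, 4%, 50% and 74% of changes of 1.5-, 2-, 4- and 8-fold were recovered, and 5 of 69 calls were false. With 2000 changed at each of 2-, 4- and 8-fold among 22863 tested, 54%, 81.3% and 86.8% were recovered and 202 of 4643 calls (4.4%) were false.

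Alternatives were the replicate number as a block, quantile normalization, centring on the median, an offset of 5.97 units (the 10th percentile of all signals) before log2, no filter, a filter at the 70th percentile, eBayes with an intensity trend and robust settings, array weights, the mean over a gene's probe sets, representatives without cross-hybridising probe set types, stricter thresholds and leaving out each array. Added after the data were seen were signals floored at each array's median, both arrays with sex-linked signals of 1 sex left out, an estimated correlation for lists that passed only in an alternative, and a search over families of genes that share the letters of their symbols. Dim genes limit the precision: a fold against a group near background depends on how low signals were treated.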

Results

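Gene expression was measured in cells of the Atoh1 lineage sorted from the mouse rhombomere 1 and isthmus region at embryonic day E14.5. Atoh1 is a proneural transcription factor of the rhombic lip, the germinal zone that gives rise to cerebellar granule cells and to neurons of several brainstem nuclei. In Swiss Webster embryos carrying Atoh1-CreER and the RCE reporter, tamoxifen given to the dam (4 mg per 35 g) switched on EGFP in cells that expressed Atoh1 around the time of dosing. The early group was labelled at E10.5 and the late group at E13.5, and EGFP-positive cells of both groups were collected by flow cytometry at E14.5. Each group held 3 samples, each hybridised to its own Affymetrix Mouse Genome 430 2.0 array, and the number of arrays limits the precision. The labels do not say whether the samples came from separate litters, so p-values measure only the spread between these samples, which may be technical. Median signals of the 6 arrays lay between 97.7 and 112 units. Spearman correlations over all probe sets were 0.938 to 0.945 among late arrays, 0.874 to 0.893 among early arrays and 0.845 to 0.885 between the groups. The ratio of the 3′ to the 5′ Actb control probe set, a sign of RNA quality, was 17.4, 19.4 and 26.3 in the early arrays against 16.1, 15.0 and 12.9 in the late arrays. For Gapdh the same ratio was 10.7 to 13.2 in the early and 9.47 to 12.1 in the late arrays. Both ratios were at least 9.47 in all 6 arrays, so these control signals were strongly weighted to the 3′ end in both groups.

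The comparison asked how cells of the Atoh1 lineage that expressed Atoh1 early differed from those that expressed it late, at 1 common age. The day of labelling and the time between labelling and collection differed together. Late cells had higher signals of Atoh1 itself, of 16 of 21 tested granule cell lineage transcription factors, of 36 of 41 G1/S and 42 of 43 G2/M cell cycle genes and of 7 of 13 hedgehog pathway genes (for these 4 lists as a whole, camera adjusted p = 0.138, 0.0805, 0.0805 and 0.127 with an estimated correlation). Early cells had higher signals of 15 of 27 transcription factors of the early lineage and brainstem nuclei, with 4 higher in the late cells, and of 24 of 32 genes of the neuronal cytoskeleton, 21 of 33 of synaptic release, 30 of 47 of ion channels and 6 of 7 of glutamate signalling. For these 5 lists as a whole, camera gave adjusted p = 0.123, 0.0805, 0.0805, 0.0805 and 0.127 with an estimated correlation. Atoh1 averaged 8642 ± 1588 units in the late and 690 ± 273 units in the early group (SD, n = 3 in each), a difference of -3.72 ± 0.36 (SE) on the log2 scale, or 13.1-fold (limma, Benjamini-Hochberg adjusted p = 0.00196). The labelling itself selected cells by Atoh1 expression, in the late group nearer to collection. A higher Atoh1 signal in late cells can therefore follow from the labelling and is no independent result. Nr4a2, a nuclear receptor of many postmitotic neurons, stood at 7682 ± 2794 units in the early and 320 ± 12.7 units in the late group (SD, n = 3), 23.0-fold apart (limma adjusted p = 0.00113). Of 11071 genes tested, 3332 (30.1%) passed an adjusted p of 0.05, of which 1792 were higher in the early and 1540 in the late group. At least 2-fold differences were found for 2463 of them, 1352 higher in the early and 1111 in the late group. On the level of probe sets, 6094 of 23491 tested passed (25.9%), 3155 higher in the early and 2939 in the late group. Which group held more of these calls turned with the arrays used: without early replicates 1, 2 and 3, 2345, 2498 and 2258 probe sets were higher in the early group and 3060, 2998 and 2906 in the late group, and genes likewise (1376, 1453 and 1355 against 1530, 1543 and 1407). Without late replicates 1, 2 and 3, 1963, 2153 and 1899 probe sets were higher in the early and 1119, 1192 and 1072 in the late group, with 1781, 1913 and 1737 genes past the threshold in all. Without early replicate 3 and late replicate 3, left out together after their sex-linked signals had been seen, 1336 probe sets and 862 genes passed. In all these fits the filter still needed 3 arrays above the median. A probe set above it in 1 group only was not tested once that group lost an array. This lowers that group's calls by construction, so part of the turn comes from the filter.

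The 12 genes with the largest differences toward the early group were Col8a1, Brinp3, Ampd3, Ptger2, Cntn5, Slc27a2, Gpc5, Smim17, Vwc2l, Cobl, Lrfn5 and Zfhx3. Zfhx3, a homeodomain zinc finger transcription factor, was the brightest of them, at 10412 ± 1261 units in the early and 319 ± 237 units in the late group (SD, n = 3), 38.6-fold apart (limma adjusted p = 0.00194). Lrfn5, a synaptic adhesion protein, stood at 1506 ± 332 against 40.9 ± 18.9 units, and Cntn5, an immunoglobulin adhesion molecule of axons, at 701 ± 165.5 against 15.7 ± 14.3 units. The 12 genes with the largest differences toward the late group were Haspin, Dscc1, Phex, Mfap4, Slc35d3, Mndal, Bub1b, Gdnf, Galnt15, Cdk5rap2, Car14 and Gpr62. Haspin, a kinase that phosphorylates histone H3 in mitosis, stood at 771 ± 310 units in the late and 13.7 ± 20.5 units in the early group. Mfap4, an extracellular matrix protein, stood at 2807 ± 61.7 against 70.1 ± 90.9 units (limma adjusted p = 0.00677), and Dscc1, which helps load the replication clamp, at 2749 ± 775 against 71.7 ± 72.2 units. In 20 of these 24 genes all 3 arrays of the dimmer group lay at or below their array's median, so the fitted folds rest on signals near background. With signals below the array median raised to it, the folds of the 24 genes ran from 1.16 to 38.6, with 14.4 for Lrfn5, 22.1 for Dscc1 and 22.5 for Mfap4. Under that floor Phex (adjusted p = 0.203), Gdnf (adjusted p = 0.158) and Gpr62 (adjusted p = 0.385, limma) no longer passed. Leaving out 1 array ended the calls of Dscc1 (limma adjusted p = 0.0783, 0.0671 and 0.0696 without late replicates 1, 2 and 3), Ptger2 (0.0955 and 0.109 without late replicates 1 and 3), Smim17 (0.0791 without late replicate 2) and Cobl (0.0563 without late replicate 3). It also ended those of Slc35d3 (limma adjusted p = 0.0548 without early replicate 1), Gpr62 (0.101 and 0.106 without early replicates 2 and 3) and Bub1b (0.0558 without early replicate 1, and 0.127, 0.114 and 0.121 without late replicates 1, 2 and 3). The 20 genes above were not tested without any 1 array of their brighter group, because the filter still needed 3 arrays. Their calls were tried only against the loss of arrays of the dimmer group.

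Granule cell lineage transcription factors were higher in the late group, among them Atoh1, on which the labelling rests. Of 21 tested members, 16 were higher in the late group, 1 was higher in the early group and 4 did not pass; adjusted over the list alone, the counts were 17 and 1. Besides Atoh1, Pax6, a paired-box factor of rhombic lip and granule cell precursors, stood at 8748 ± 566 units in the late and 1254 ± 458 units in the early group (SD, n = 3), 7.29-fold apart (limma adjusted p = 0.00224). Insm1, a zinc finger factor of neurogenic progenitors, was 5.82-fold higher in the late group, and Barhl1, a homeobox factor of the granule cell and brainstem lineages, was 4.89-fold higher, with 2104 ± 385 against 434 ± 102 units. The list's median log2 difference was -1.64 (camera adjusted p = 1.62e-07). That call was lost in camera with an estimated correlation and its fewer degrees of freedom (camera adjusted p = 0.138).

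Hedgehog pathway genes were higher in the late group for 7 of 13 tested members, and no member was higher in the early group. The count adjusted over the list alone was also 7. Gli2, a transcriptional effector of the pathway, stood at 3603 ± 452 units in the late and 255 ± 134 units in the early group (SD, n = 3), 15.7-fold apart (limma adjusted p = 0.00249). Gas1, a hedgehog co-receptor, was 8.70-fold higher in the late group, Smo, the pathway's membrane transducer, 6.34-fold and Boc, another co-receptor, 5.62-fold. The list's median was -0.88 (camera adjusted p = 0.00174; adjusted p = 0.127 with an estimated correlation).

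Cell cycle genes were higher in the late group almost throughout. Of 41 tested genes of G1/S and DNA replication, 36 were higher in the late group and none in the early group, and 40 were higher in the late group when adjusted over the list alone. Mcm2 and Mcm3, subunits of the replicative helicase, were 8.78-fold and 11.03-fold higher in the late group, Mcm2 at 5568 ± 284 against 637 ± 78.9 units (SD, n = 3; limma adjusted p = 0.00113). Of 43 tested G2/M genes, 42 were higher in the late group and none in the early group, and all 43 were higher in the late group when adjusted over the list alone. Kif20a, a kinesin of cytokinesis, stood at 1060 ± 124.5 units in the late and 83.4 ± 11.9 units in the early group, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at 1357 ± 279 against 91.5 ± 26.5 units. The median log2 differences were -2.23 for G1/S and -2.88 for G2/M genes (camera adjusted p = 2.93e-18 and 2.41e-21). Neither call held in camera with an estimated correlation and its fewer degrees of freedom (camera adjusted p = 0.0805 for each). The calls of Pole, a DNA polymerase subunit, and Bub1b, a spindle checkpoint kinase, were lost without late replicate 1 (limma adjusted p = 0.074 and 0.127), as they were without late replicate 2 (0.0663 and 0.114) or late replicate 3 (0.0721 and 0.121), and that of Bub1b also without early replicate 1 (0.0558).

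Members of the list of cell cycle exit genes moved both ways: of 16 tested, 3 were higher in the early and 6 in the late group, and 3 and 8 when adjusted over the list alone. Cdkn1c, an inhibitor of cyclin-dependent kinases, was 4.86-fold higher in the early group, at 4395 ± 536 against 933 ± 284 units (SD, n = 3; limma adjusted p = 0.00366). Rbl1, a retinoblastoma relative expressed in cycling cells, and Gadd45g, a growth arrest gene of newly formed neurons, were higher in the late group, 4.24-fold and 3.23-fold. Of 19 tested Notch pathway genes, 6 were higher in the late and 2 in the early group, and 9 and 3 when adjusted over the list alone. Hey1 and Hes6, both relatives of the Hes repressors, were 4.08-fold and 3.47-fold higher in the late group. Of 25 tested Wnt and BMP pathway genes, 9 were higher in the late and 3 in the early group, and 11 and 3 when adjusted over the list alone. Id4, an inhibitor of basic helix-loop-helix factors, was 22.01-fold higher in the early group, at 14473 ± 2195 against 675 ± 219 units, and Wnt7a, a secreted ligand, stood at 418 ± 123 against 34.8 ± 16.4 units. Nkd1, a feedback inhibitor of Wnt signalling, was 6.51-fold higher in the late group. None of these 3 lists passed as a whole (camera adjusted p = 0.219 for cell cycle exit, 0.124 for Notch and 0.107 for Wnt and BMP). The Wnt and BMP list passed when any 1 early array was left out (camera adjusted p = 0.00707, 0.0427 and 0.0374 without early replicates 1, 2 and 3). In the same fits camera gave adjusted p = 0.16, 0.276 and 0.423 with an estimated correlation. These fits tested only 21, 22 and 22 of the 25 genes, because the filter still needed 3 arrays. Members above the medians in the early group only, such as Wnt7a, dropped out, which moves the list's median toward the late group.

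**Figure D1:**
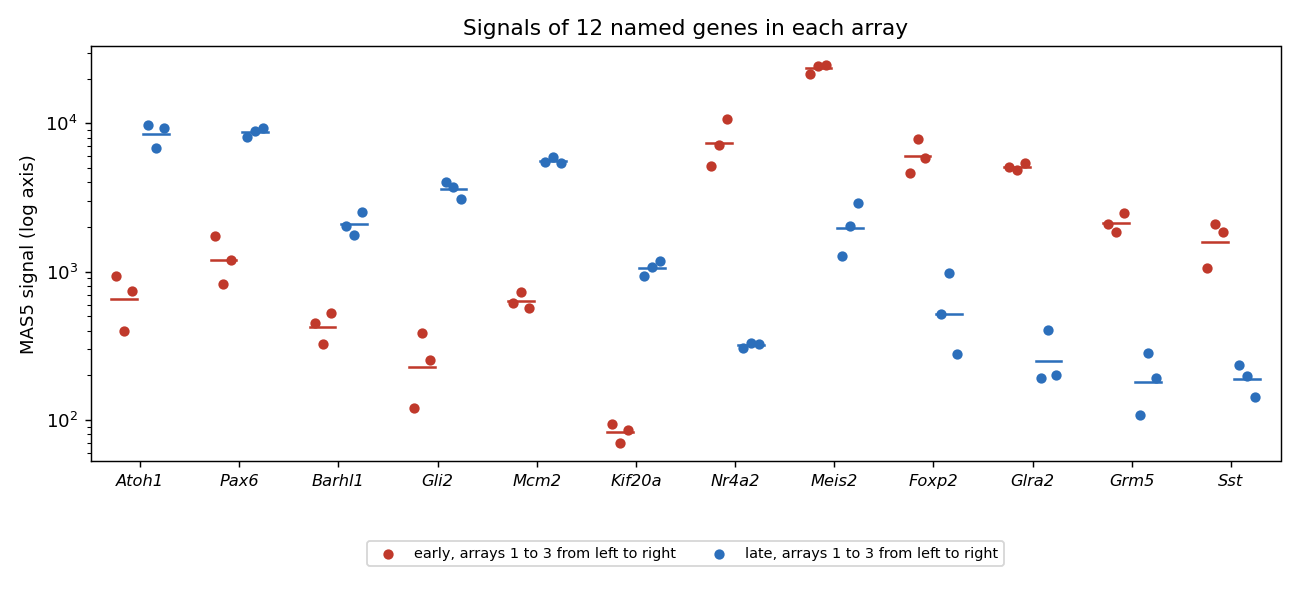
MAS5 signal (log axis) of 12 named genes in each of the 6 arrays, with points for single arrays and bars at the geometric mean of each group. In each of these genes the 3 arrays of the early group lie apart from the 3 late arrays, below them from Atoh1 to Kif20a and above them from Nr4a2 to Sst.

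Transcription factors of the early Atoh1 lineage and of brainstem nuclei were mostly higher in the early group. Of 27 tested members, 15 were higher in the early and 4 in the late group, and 16 and 4 when adjusted over the list alone. Next to Nr4a2, Meis2, a TALE homeobox factor, stood at 23496 ± 1776 units in the early and 2072 ± 802 units in the late group (SD, n = 3), 11.9-fold apart (limma adjusted p = 0.00164). Lmo3, a LIM-domain cofactor, and Foxp2, a forkhead factor also found in Purkinje cells, were 12.2-fold and 11.5-fold higher in the early group. The members higher in the late group, named after their values were seen, were Eomes at 1569 against 472 units, Pou4f1 at 252 against 91.5 units, Satb1 and Tcf4. Eomes is a T-box factor of unipolar brush cell precursors. The list's median was 1.21 (camera adjusted p = 1.05e-04; adjusted p = 0.123 with an estimated correlation).

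Of 15 tested positional identity genes of isthmus and hindbrain, 2 were higher in each group, and likewise when adjusted over the list alone. Irx3 and Irx5, Iroquois homeobox factors of anterior-posterior patterning, were 10.03-fold and 4.51-fold higher in the early group. Otx2, a homeobox factor of midbrain and of part of the rhombic lip, stood at 1970 ± 262 units in the late and 193 ± 44.6 units in the early group (SD, n = 3; limma adjusted p = 0.00117). En2, a homeobox factor of midbrain and rhombomere 1, was 1.73-fold higher in the late group, a call lost without late replicate 1, 2 or 3 (limma adjusted p = 0.0673, 0.0545 and 0.0823). The list as a whole did not pass (median 0.34, camera adjusted p = 0.797).

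Genes of neuronal maturation were higher in the early group. Of 32 tested genes of the neuronal cytoskeleton and maturation, 24 were higher in the early group and none in the late group, and 29 and 1 when adjusted over the list alone. Vsnl1, a neuronal calcium sensor, stood at 1732 ± 602 units in the early and 65.7 ± 53.2 units in the late group (SD, n = 3; limma adjusted p = 0.00366), while Rbfox1 and Celf4, RNA-binding proteins of neurons, were 11.4-fold and 8.66-fold higher. Of 33 tested synaptic vesicle and release genes, 21 were higher in the early and 1 in the late group, and 24 and 1 when adjusted over the list alone. Dnm1, the dynamin of synaptic vesicle retrieval, stood at 4205 ± 611 against 408 ± 68.7 units, and Rab3c, a vesicle GTPase, at 4147 ± 805.5 against 417 ± 68.1 units. Of 47 tested ion channel and ionotropic receptor genes, 30 were higher in the early and 2 in the late group, and 32 and 3 when adjusted over the list alone. Glra2, a glycine receptor subunit of embryonic neurons, was 20.5-fold higher in the early group (5119 ± 266.5 against 265 ± 120 units), and Scn2a, a voltage-gated sodium channel, 22.15-fold. Chrnb4, a nicotinic receptor subunit, was higher in the late group at 363 ± 118 against 51.9 ± 73.35 units (limma adjusted p = 0.0458), a call lost without late replicate 1 (adjusted p = 0.132), 2 (0.11) or 3 (0.106) and without early replicate 1 (0.0807) or 2 (0.0981). The medians of the 3 lists were 1.29, 1.41 and 1.44 (camera adjusted p = 8.54e-12, 6.66e-09 and 2.05e-09). None of the 3 calls held in camera with an estimated correlation and its fewer degrees of freedom (camera adjusted p = 0.0805 for each). Beside these groups, the 3′ to 5′ ratio of Actb was higher in all 3 early arrays than in any late array.

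Glutamate signalling genes were higher in the early group for 6 of 7 tested members, none was higher in the late group, and the count adjusted over the list alone was also 6. Grm5 and Grm3, metabotropic glutamate receptors, stood at 2145 ± 309 and 1134 ± 128 units in the early group against 194 ± 87.2 and 119 ± 60.1 units in the late group (SD, n = 3; limma adjusted p = 0.002285 and 0.00359). Slc1a1, a neuronal glutamate transporter, was 12.2-fold higher. The vesicular glutamate transporter gene Slc17a6, named after its values were seen, stood at 5123 units in the early and 1411 units in the late group. The list's median was 3.39 (camera adjusted p = 2.29e-04; adjusted p = 0.127 with an estimated correlation). Among neuropeptides and their receptors, 9 of 18 tested genes were higher in the early and 2 in the late group, and 13 and 2 when adjusted over the list alone. Oprl1, the nociceptin receptor, was 9.57-fold and Sst, somatostatin, 8.47-fold higher in the early group, Sst at 1662 ± 546 against 192 ± 45.2 units. Sstr2, a somatostatin receptor, was 5.39-fold higher in the late group (1883 ± 219 against 352 ± 60.1 units, limma adjusted p = 0.0016). The median of that list was 1.45 (camera adjusted p = 0.00212; adjusted p = 0.189 with an estimated correlation).

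Other transmitter lists held few tested genes. Of 7 GABAergic and glycinergic lineage genes, Gad2 and Gad1, the enzymes that make GABA, were higher in the early group, 3.23-fold and 2.63-fold (limma adjusted p = 0.0166 and 0.0486), also when adjusted over the list alone. The call of Gad1 was lost without early replicate 1 (limma adjusted p = 0.106) or 3 (0.106) and without late replicate 1 (0.0977), 2 (0.123) or 3 (0.146), and that of Gad2 without late replicate 1 (0.0625) or 3 (0.062). The list did not pass (median 1.21, camera adjusted p = 0.126). Of 2 cholinergic genes tested, Nos1, neuronal nitric oxide synthase, was 1.80-fold higher in the early group (limma adjusted p = 0.033), and both passed when adjusted over the list alone. The call of Nos1 was lost when any 1 array other than early replicate 2 was left out (limma adjusted p from 0.066 to 0.0976). Of 8 monoaminergic genes only En2, a patterning gene, passed, also when adjusted over the list alone (list median -0.25, mean 0.01, camera adjusted p = 0.602).

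Axon guidance and neuronal migration genes moved both ways, with 22 of 65 tested genes higher in the early and 14 in the late group, and 29 and 19 when adjusted over the list alone. Chl1, a cell adhesion molecule of the L1 family, stood at 21275 ± 1997 units in the early and 819 ± 466 units in the late group (SD, n = 3), 28.7-fold apart (limma adjusted p = 0.00143). Unc5d, a netrin receptor, was 25.5-fold and Epha4, an ephrin receptor, 7.499-fold higher in the early group. Among genes of this list higher in the late group, named after their values were seen, were Cxcr4, the chemokine receptor of granule cell precursors, at 3221 against 533 units, Epha3 at 6410 against 1127 units and Unc5c at 7089 against 2153 units. The median was 0.10 (camera adjusted p = 0.349).

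**Figure D2:**
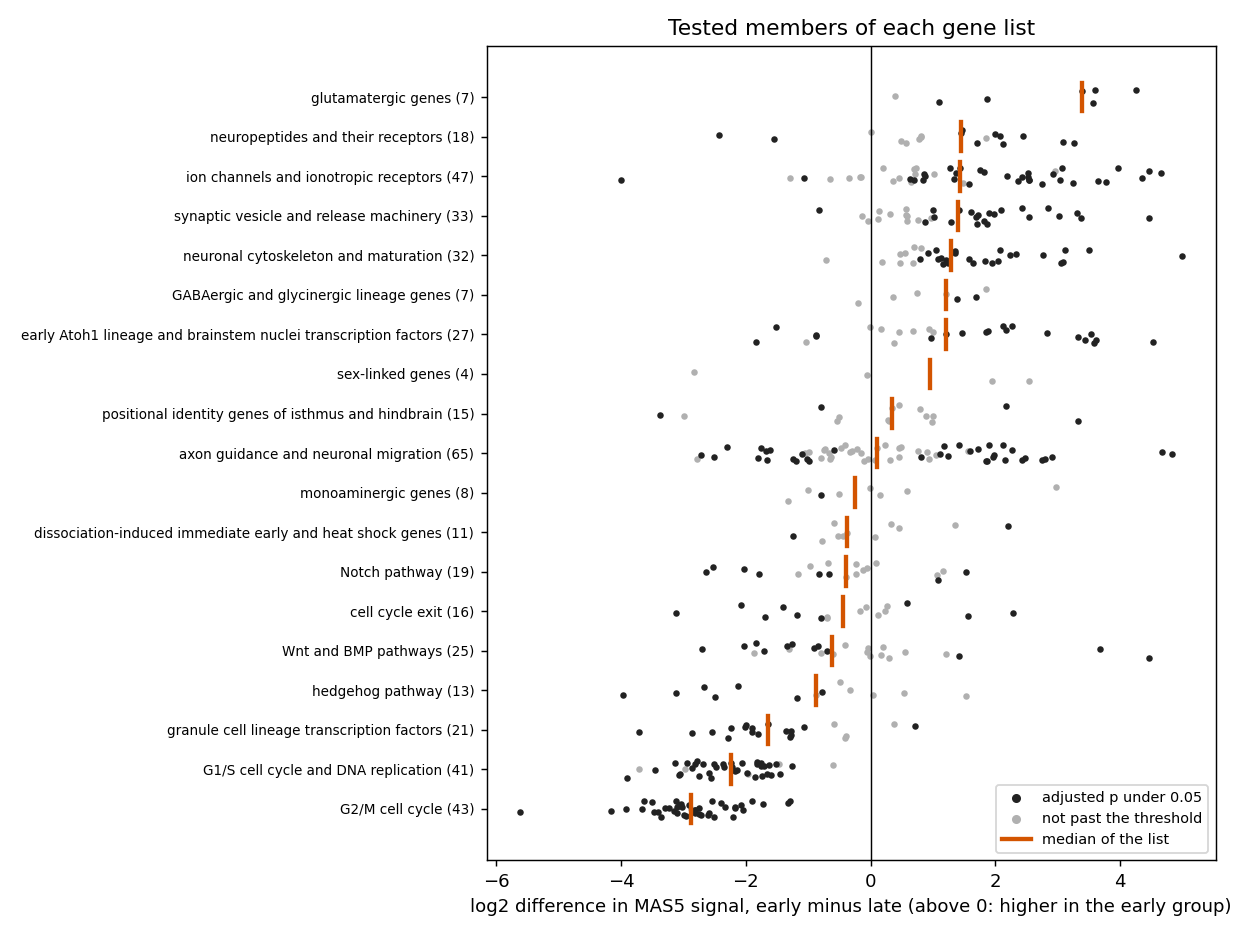
Log2 difference in MAS5 signal (early minus late) of each tested member of the 19 gene lists with at least 3 tested genes; numbers in parentheses are tested members, dark points passed an adjusted p of 0.05, grey points did not, and orange bars mark list medians. The G2/M (median -2.88) and G1/S (-2.23) lists lie almost wholly on the late side, and the glutamatergic list (3.39) has the highest median on the early side.

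In all, camera with its preset correlation of 0.01 passed 10 of the 25 lists with at least 3 tested members, none of the 10 calls held with an estimated correlation, and fry passed 16, among them the marker lists of Purkinje cells, oligodendrocyte precursors and microglia. Groupings of the 6 arrays that mixed the labelling days gave from 5 to 15 lists past the same preset-correlation threshold and at most 2 probe sets. In these groupings part of the early-late difference stayed in the contrast and the rest entered the spread. They therefore do not show what chance alone would give.

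Of 11 tested radial glial and neural stem cell markers, 3 were higher in the early and 2 in the late group, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.797), and only Ptprz1 and Vim kept their call in every fit without 1 array. Fabp7, a fatty acid binding protein higher in the early group and named after its values were seen, and Slc1a3, a glial glutamate transporter higher in the late group, each lost it in 5 of these 6 fits (limma adjusted p from 0.051 to 0.111 and from 0.0688 to 0.116). Aldh1l1, an astrocyte enzyme higher in the early group, lost it without late replicate 1 (0.0833) or 3 (0.0804), and was not tested without any 1 early array. Ptprz1, a receptor phosphatase of glial progenitors, was 5.47-fold higher in the early group, and Vim, vimentin, was 2.12-fold higher in the late group (25962 ± 2640 against 12235 ± 486 units, SD, n = 3; limma adjusted p = 0.00744). Purkinje cell markers had 2 of 6 tested genes higher in the early group, 3 when adjusted over the list alone (median 1.28, camera adjusted p = 0.126). These were Foxp2, which the list of early lineage factors also holds, and Calb1, a calcium buffer, at 1320 ± 462 against 124 ± 32.0 units. Of 4 oligodendrocyte precursor markers, Olig1 and Olig2 were higher in the early group, Olig1 at 2149 ± 292 against 164 ± 58.2 units, and Pdgfra was higher in the late group (camera adjusted p = 0.332), with the same counts when adjusted over the list alone. The call of Pdgfra was lost without late replicate 1 (limma adjusted p = 0.0566). Of 6 mesenchymal markers 1 passed (Postn, 188 ± 57.1 units in the early and 28.6 ± 34.0 in the late group), also when adjusted over the list alone. Of 3 microglial and leukocyte markers 1 passed (Csf1r, 510 ± 244 against 136 ± 27.8 units), and 2 when adjusted over the list alone. Without late replicate 1 or 3 neither Postn (limma adjusted p = 0.0761 and 0.111) nor Csf1r (0.0897 and 0.074) passed, and Csf1r also failed without early replicate 1 (0.0634) or late replicate 2 (0.0645). Postn was not tested without any 1 early array. None of the 4 endothelial markers passed, with Kdr at 194 ± 91.8 against 69.4 ± 76.2 units, nor did the only erythroid marker tested, Hbb-y; the counts adjusted over the list alone were the same. Of 2 choroid plexus markers only Otx2, which the positional list also holds, was higher in the late group, also when adjusted over the list alone. The lists of mesenchymal (camera adjusted p = 0.332), microglial (0.126) and endothelial markers (0.384) did not pass as a whole.

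Of 11 tested immediate early and heat shock genes that tissue dissociation can induce, Hspa1b, an inducible chaperone, was 4.599-fold higher in the early group and Ier2, an immediate early gene, 2.37-fold higher in the late group (limma adjusted p = 0.0167 and 0.00778), also when adjusted over the list alone. Without late replicate 1 or 2 the call of Hspa1b was lost (limma adjusted p = 0.0541 and 0.0586). The list did not pass (median -0.37, mean 0.04, camera adjusted p = 0.73). None of the 4 sex-linked genes passed the threshold, also when adjusted over the list alone (camera adjusted p = 0.82), but single arrays stood apart. The groups did not overlap for Xist (limma adjusted p = 0.232) or Eif2s3y (0.29). Xist, the RNA of the inactive X chromosome, gave 10545, 8141 and 166 units in early arrays 1, 2 and 3 and 14178, 18008 and 19797 units in the late arrays. Eif2s3y, a Y-linked gene, gave 1077, 1131 and 1772 units in the early arrays and 826, 942 and 14.1 units in the late arrays.

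**Figure D3:**
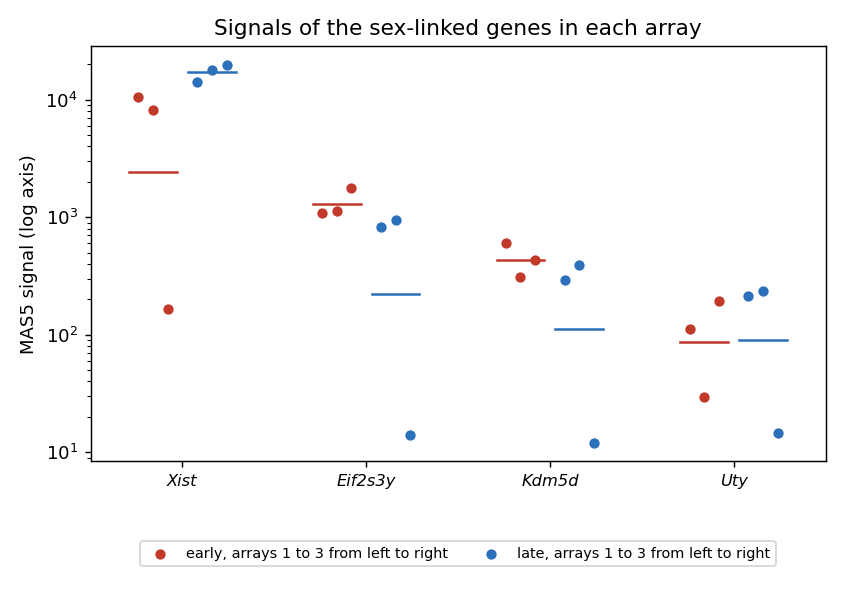
MAS5 signal (log axis) of Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty in each array, with points for single arrays in the order of their replicate numbers and bars at the geometric mean of each group. Xist is low only in early array 3 (166 units), and the 3 Y-linked genes are lowest in late array 3 (14.1, 12.1 and 14.6 units).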

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

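The floored signals, the omission of early replicate 3 with late replicate 3 and the estimated correlation for lists that passed only in an alternative were chosen after the data were seen; the cause of the changes below was not tested unless given. The main counts were 6094 probe sets and 3332 genes. Replicate numbers did not pair the samples (correlations of the deviations of same-numbered arrays -0.0293, -0.0748 and -0.00517; 0 of 6 samples correlated best with its own number), and with the number as a block 3590 probe sets passed (2003 higher early, 1587 higher late) and 1983 genes (1139 and 844), with fewer residual degrees of freedom. Without a filter, with 45037 probe sets tested, 2719 probe sets (1559 and 1160) and 1478 genes (893 and 585) passed. At an adjusted p of 0.01 the counts were 2433 probe sets (1449 and 984) and 1427 genes (875 and 552). Without both arrays of 1 sex, 1336 probe sets (768 and 568) and 862 genes (502 and 360) passed, from 4 arrays. In this fit and in those without 1 array the filter still needed 3 arrays. Probe sets above the medians in 1 group only were not tested once that group lost an array, which lowers its calls by construction. Leaving out 1 array gave 2971 to 5496 probe sets (1899 to 2498 higher early, 1072 to 3060 higher late) and 1737 to 2996 genes (1100 to 1453 and 637 to 1543); the lowest counts of probe sets were those without late replicate 1 (3082), 2 (3345) or 3 (2971), and without any 1 early array the late group held more calls than the early group (43.4% to 45.5% of probe sets higher early). Quantile normalization, centring, the offset, the stricter filter, trend and robust eBayes, array weights and the floor gave 5744 to 7185 probe sets, of which 47.8% to 51.6% were higher early, against 51.8% in the main setting; 4515 to 6089 of them were among the main 6094. With an estimated correlation none of the 10 lists that passed camera did so: granule factors (median -1.64), early lineage factors (1.21), G1/S (-2.23), G2/M (-2.88), hedgehog (-0.88), cytoskeleton (1.29), synaptic (1.41), ion channels (1.44), glutamatergic (3.39) and neuropeptides (1.45), with adjusted p from 0.0805 to 0.189. Fry passed 16 lists, those 10 with cell cycle exit (-0.43), Wnt and BMP (-0.61), axon guidance (0.10) and, all toward the early group, the marker lists of Purkinje cells (median 1.28, fry adjusted p = 0.0143), oligodendrocyte precursors (0.86, 0.00553) and microglia (1.79, 0.0357). The Wnt and BMP list passed under the stricter filter (-1.25), without both arrays of 1 sex (-0.74) and without early replicate 1, 2 or 3, where leaving out 1 array gave medians from -0.81 to -0.61. In none of these 5 fits did it pass with an estimated correlation (camera adjusted p from 0.0713 to 0.479). They tested 11 to 22 genes of the list, against 25 in the main setting, so the filter changed its members. The cholinergic list, with no test in the main setting for want of tested genes, had a median of 1.11 without a filter and passed there (camera adjusted p = 0.0104; adjusted p = 0.133 with an estimated correlation). Calls of the other gene and marker lists kept their side of the threshold wherever they were tested. Medians of the monoaminergic, axon guidance and sex-linked lists, none past the threshold in the main setting, changed sign in some settings. Of the 97 named genes past the threshold, 63 stayed past it in every alternative in which they were tested, 22 lost it in at least 1 fit without 1 array, and none reversed. Without a filter 25 named genes lost their call, bright ones such as Vim and En2 among them. Signal over background limits dim genes: with the floor Phex, Gdnf, Gpr62 and Aldh1l1 lost their call, each with the mean of 1 group under the median of every array.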

Other observations

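Families of genes that share the letters of their symbols, searched after the data were seen, added groups that no list above held. Of 168 families with at least 8 tested genes, 16 passed camera with its preset correlation, and none did with an estimated correlation. Calcium/calmodulin-dependent kinases and their inhibitors (Camk) were higher in the early group for 9 of 10 tested genes and none was higher in the late group (median 1.66, camera adjusted p = 0.00137; adjusted p = 0.447 with an estimated correlation). Camk2a stood at 275, 716 and 581 units in the early and 51.0, 73.2 and 80.6 units in the late arrays, 2.86 ± 0.40 (SE) apart on the log2 scale (limma adjusted p = 0.00528), and Camk4 did not pass (0.38 ± 0.28). Of 11 clustered protocadherins of the beta group (Pcdhb), cell surface proteins of neuronal identity, 6 were higher in the early and none in the late group (median 1.15, camera adjusted p = 0.0136; adjusted p = 0.447 with an estimated correlation). Signals of these closely related genes are uncertain gene by gene because probe sets can take up transcripts of relatives. Of 15 genes with the letters Rgs, 14 regulators of G protein signalling and Rgs7bp, a binding protein of one of them, 6 regulators were higher in the early and none in the late group, while Rgs7bp was higher in the late group (limma adjusted p = 0.0499; for all 15, median 1.00, camera adjusted p = 0.0159; adjusted p = 0.569 with an estimated correlation), with Rgs8 at 1038, 716 and 745 against 93.7, 57.8 and 50.4 units.

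Late cells had higher signals of nucleoporin genes (Nup), 8 of 18 tested with none higher in the early group (median -0.67, camera adjusted p = 0.00354; adjusted p = 0.447 with an estimated correlation), and of DEAD-box helicase genes (Ddx), 8 of 31 with 2 higher in the early group (median -0.53, camera adjusted p = 0.00493; adjusted p = 0.447 with an estimated correlation). Nup107 stood at 458, 463 and 385 units in the early and 1463, 1337 and 1279 units in the late arrays.

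Signals that stood out in single arrays are given as values. Cryab gave 794 units in early array 1 against 2.6 to 27.4 units in the other 5, and Ccn2 gave 578 against 1.5 to 32.6 units, the only 2 probe sets at 500 units or more that lay at least 16-fold above each other array. Hspa1a, Hspb1 and Acta2 were also highest in early array 1, at 2560, 759.5 and 1591 units. Hbb-y gave 4657 units in early array 3, at most 13 units in early arrays 1 and 2, and 233 to 326 units in the late arrays. Ttr gave 1547 units in late array 3 and at most 151 units elsewhere. Hoxb3 gave 18.1 units in late array 1, against 977 to 1111 in the other late arrays.

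The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixed both labelling days in each of its groups. The early-late difference then entered the spread within groups, which lowers calls by construction, and part of it stayed in the contrast. The other splits therefore do not show what chance alone would give, for probe sets, genes or lists. The real split gave 6094 probe sets, against at most 2 in another split, so 1 of the 10 gave as many. It gave 3332 genes, against 0 in each other split, so again 1 of the 10. It gave 10 lists past camera's preset-correlation threshold, against at most 15 in another split, and 5 of the 10 splits gave as many.

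The tests on the lists were written before their results were seen, and those on the spread after that spread had been noticed but before the values that decide them. Cell cycle lists were higher in the late group. Progenitors outside the Atoh1 lineage, such as radial glia, would raise radial glial markers in the late group by about the G2/M median of 2.88 on the log2 scale, and a value under 1.44 was set beforehand to count against them. The markers' median, late minus early, was -0.152. The largest late-direction value of any of the 11 tested markers was 1.08 (Vim), so the markers did not rise as a set. The bound assumed equal log2 rises in both lists, yet Vim already averaged 12235 units in the early group. With 3 markers higher in the early and 2 in the late group, a rise in the late sort could also be offset. The test therefore cannot exclude such cells. A hypothesis that stays open is that late cells, labelled nearer to collection, held more dividing granule cell precursors. The day of labelling and the time from labelling to collection differed together, and this hypothesis was not tested.

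Neuronal maturation lists were higher in the early group. Neurons of other lineages carried along in the sort would raise Purkinje cell markers (6 tested, of which Foxp2 and Lhx1 are also early lineage factors) and GABAergic genes too. The medians of these lists, 1.28 and 1.21, lay between the synaptic list's median of 1.41 and 0.705, the level under which the explanation would have been argued against, so such cells cannot be told apart from maturation of the labelled cells. Camera did not pass either list (adjusted p = 0.126 for each), while fry, which does not compare a list with other genes, passed the Purkinje cell markers (adjusted p = 0.0143). Early and late means were 340 and 108 units for Gad2, 362 and 128 for Gad1 and 1320 and 124 for Calb1. The sort for EGFP was meant to remove unlabelled neurons, but its purity was not tested here.

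Early arrays differed more among themselves than late arrays, with a median SD of 0.386 against 0.212 on the log2 scale over the tested probe sets. Noise in dim probe sets would leave the 5873 brightest probe sets alike, but there the lowest early pair still differed 1.41 times as much as the highest late pair. The sex of the embryos was taken to remove the gap once early array 3 and late array 3 were left out, and the remaining early pair differed 1.72 times as much as the late pair. The arrays left still carried signals of both sexes, and a median over all tested probe sets hardly depends on a few sex-linked genes. With only the remaining pair in each group, this test cannot exclude sex. A share of late-type cells that differs between early arrays stays open: the largest correlation of an early array's deviations with the early minus late difference, across probe sets that are not independent, was 0.164 in size, between the bounds of 0.3 and 0.1 set for either answer. RNA quality was not tested as a cause. The 3′ to 5′ ratio of Actb was 17.4, 19.4 and 26.3 in the early arrays against 16.1, 15.0 and 12.9 in the late arrays. For Gapdh the ratios of the groups overlapped. A wider range of cell types among early-labelled cells is a hypothesis that was not tested and cannot be told apart from such a technical cause here.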
